A study of Mus musculus with 2 samples.

How the data were processed

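The series holds 2 libraries of CD45-sorted immune cells of the mouse colon, 1 from colon tumours of ApcMin/+ mice and 1 from normal colon of wild-type mice, prepared with collagenase IV and DNase I and the 10x Genomics 3′ v3 kit, per the labels. The series text names the inDrops platform instead, and the headers of the matrices are those of 10x Genomics software. How many mice were pooled in a library is not stated. The deposited processed files were used as they were: a matrix of raw UMI counts per library, 1 table of counts, 1 table of normalized values and 1 table of cell annotations. The deposited counts are UMI counts per gene and cell made with Cell Ranger 5.0.1 and the mm10 genome, per the labels, and the matrix headers name version 5.0.0. The deposited normalized values are the natural log of 1 plus the count per 10000 UMIs of the cell, tested in every cell, with a largest difference of 7.1e-15. The mitochondrial percent of each cell was given by the authors in the cell table. The clustering method of the authors' 31 clusters and the method behind their 8 class names are not given in the sources used here.

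The count table holds 21482 genes and 23922 cells, the number that the series text states. The authors kept 14445 of 16028 tumour barcodes and 9477 of 10312 wild-type barcodes. The kept cells had 206 to 3997 genes and 500 to 41555 UMIs in the tumour library and 224 to 3997 genes and 501 to 59169 UMIs in the wild-type library, with under 15% mitochondrial UMIs. Of the tumour barcodes left out, 214 had 200 genes or fewer, 498 had 4000 or more and 1063 had a mitochondrial share of 15% or more. The wild-type counts were 25, 256 and 579. Another 15 tumour barcodes and 0 wild-type barcodes were left out inside all 3 limits. The column sums of the count table equalled the totals of the cell table in 23922 cells. In the table, 2403 genes had 0 UMIs in every cell, and 318 of these have symbols that the feature files lack. Over 21137 shared genes, 1383 tumour entries and 1939 wild-type entries differed from the matrices. Of the columns of the cell table, 1 was not used, since it names the tumour cells by another label, PBS_immune, and the sources used here do not say whether these mice were treated.

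Counts of the cells of a class were summed per library and scaled by the total of that sum to CPM. A level has an exact Poisson interval, a ratio of 2 levels an exact conditional binomial interval and a share of cells a Clopper-Pearson interval, all at 95%. With 1 library per group, no test between groups was possible, and no p-value is given. The limit of a share of 0 and the floor of a level with 0 counts are 3 counts. A class was compared where each library held 20 cells or more. The comparisons, the gene lists and the first alternatives were written before the data were examined, and what was set or added later is named below.

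Classes are those of the authors. The T cell and DC classes were divided further by Leiden clustering of their cells with scanpy, on 2000 variable genes, 30 principal components and 15 neighbours, at a resolution of 1 for T cells and 0.6 for DC, with random seed 1. This gave 29 T cell and 8 DC sub-clusters. The limits that name a sub-cluster were set after the data were seen. A Treg-like sub-cluster had 100 CPM of Foxp3 or more and 3 Treg markers. A CD4 sub-cluster had 90 CPM of Cd4 or more and 30 of Cd8a at most, and a CD8 sub-cluster 75 of Cd8a or more and 30 of Cd4 at most. Naive T cells had 400 CPM of Lef1 or more and also met a limit on a second gene. γδ T cells had 300 CPM of Trdc or more and 300 of Cd8a at most. Innate lymphocytes had 100 CPM of Cd3e at most, and ILC2 a marker score of 1. mregDC-like cells had 1000 CPM of Fscn1 or more, plasmacytoid DC 500 of Siglech, type 1 DC 100 of Xcr1 and type 2 DC a marker score of 1. A score is the mean log2 fold of markers over the other cells. T cell sub-clusters with a B cell score of 1 or a neutrophil score of 1.5 or more were called mixed. This rule was not applied to DC, where sub-cluster DC 0 had a neutrophil score of 1.82. A sub-cluster lost its name where its 10 leading genes held more markers of another class. For naive and other CD4 T cells, Treg markers did not count as another class, so sub-clusters T cell 11 and T cell 23, whose leading genes held Treg markers, stayed other CD4 T cells. The design named mregDC, type 1 and type 2 DC as the denominator of the mregDC share. After no tumour sub-cluster was named type 2 DC, all DC without plasmacytoid DC were used, and the text prints both shares. A class was compared by cluster number where the 10 leading genes of a cluster held more markers of another class, which held for clusters 10, 13 and 23, and for cluster 20, which led with division genes. A marker counted at 50 CPM and a log2 fold of 1.

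Doublets were scored per library with Scrublet in scanpy at an expected 6%. It called 675 tumour cells, 4.67%, and 1 wild-type cell, 0.0106%. The tumour threshold of 0.213 applied to both libraries gave 675 and 664 cells. Cells called doublets were kept in the main values. Per the series text, the authors had already removed putative doublets and stressed or dead cells.

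The genes named for a class are the 10 highest and 10 lowest in Treg, CD8 T cells, macrophages, monocytes and DC, and the 4 highest and 4 lowest in the other classes. They have 30 UMIs and 50 CPM or more in the library where they are higher and are ranked by the interval bound of the ratio nearest to 1. Mitochondrial, ribosomal protein, haemoglobin, immunoglobulin, T cell receptor and sex-specific genes and unnamed gene models are excepted. A gene under 10% of its highest class in the same library was set apart as possible free RNA. Members of the lists with the 2 highest and 2 lowest ratios at 50 CPM or more are named as well, haemoglobin and immunoglobulin genes included. Further named genes are Foxp3, Ctla4, Il2ra, Ccr8, Ccr4 and Icos in Treg, Ccr7, Lamp3, Fscn1, Ccl22, Ccl17, Cd274, Pdcd1lg2, Cd80, Cd86, Cd40, Il12b, Il15, H2-Ab1, H2-Aa and Cd74 in mregDC, and Apc. Some genes that these rules pick are not reported here. Genes shared over the classes are those at least 2-fold apart in all classes or all but 1. Other genes named within a library were picked after their values were seen, as were the 12 genes whose position is given.

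The 26 gene lists are MHC class II and class I presentation, DC maturation, DC costimulation, DC immune regulation, Treg effector, exhaustion and checkpoint, cytotoxicity, naive and central memory, gut homing, type 17, type 2, type I interferon, interferon gamma, chemokines, inflammatory cytokines, tumour-associated macrophage, resident macrophage, hypoxia and glycolysis, proliferation, dissociation stress, and epithelial, stromal, erythroid and platelet, immunoglobulin and intestinal Wnt target transcripts. A member was measured with 20 UMIs or more over both sums and called higher or lower at 1.5-fold. A list needed 3 measured members. Its median log2 ratio was placed among 10000 random lists matched in 20 expression bins, and its interval comes from 200 Poisson draws of the counts. Which lists are described for which class was chosen after the data were seen. Proliferation is also given as the share of cells with 2 or more list genes after thinning to 1000 UMIs.

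Gene positions come from GENCODE vM21 on GRCm38, matched by the gene identifiers of the feature files. Software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, scikit-learn 1.9.0 and matplotlib 3.10.9.

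The ratio and list steps were tested on counts drawn from the real means and depths of each class, with 200 genes changed by 1.5, 2 or 4-fold. No spread between animals or libraries was drawn, so this covers counting error only. A class had 6355 to 12034 genes, and 2-fold shares rest on part of the 200. The true ratio lay inside its interval for 96.1% of unchanged and 98.6% of 2-fold genes in Treg. The shares were 96.3% and 91.5% in other CD8 T cells, 96.8% and 95.9% in naive CD8 T cells and 96.1% and 93.8% in macrophages. They were 96.6% and 98.7% in monocytes, 96.1% and 96.6% in DC and 96.7% and 96.5% in naive CD4 T cells. Other CD4 T cells had 96.6% and 92.6%, γδ T cells 96.5% and 98.4% and NK cells 96.3% and 98.7%. B cells had 95.5% and 96.5%, germinal centre B cells 96.3% and 93.9%, plasma cells 96.8% and 91.0% and neutrophils 97.4% and 96.8%. For the genes changed 1.5 and 4-fold, the shares were 98.3% and 97.1% in Treg. A list of 20 genes raised 2-fold reached percentile 100 in all 14.

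The alternatives were cells with 1000 UMIs or more, cells without called doublets, a median-of-ratios size factor over genes with 50 UMIs in each sum, a total without mitochondrial, ribosomal protein and immunoglobulin genes, equal weight per cell, the authors' normalized values, minimums of 100 and 1 UMI for a list member, own clustering of all cells, other denominators, gene-based definitions of mregDC and Treg, and no thinning. Another 16 were added after the data were seen. They were the tumour Scrublet threshold in both libraries, leaving out mixed clusters, named DC as the denominator, another Leiden resolution for DC and for T cells, lists without members under 10% of their highest class, the mregDC share and the mregDC comparison without DC over the neutrophil score limit, the Treg comparison without the sub-cluster at 80 to 100 CPM of Foxp3, and other ways of naming T cell sub-clusters for the Treg share and the shares of the T cell class. Those were 80 CPM of Foxp3 for Treg, mixed sub-clusters named by their T cell genes, the other resolution without the rule on leading genes, both of these together, and γδ T cells from 200 CPM of Trdc without the Cd8a maximum, which was also applied to the genes and lists of that class. The resolution was 1.5 for T cells and 1 for DC in that alternative. Barcodes outside the authors' limits were used in 2 checks only, for the limit of 4000 genes and the mitochondrial limit, in which each was assigned to 1 of 20 class profiles of 2000 genes. Barcodes with 200 genes or fewer were not examined.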

Results

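Immune cells of the mouse colon were profiled by single-cell RNA sequencing in 2 libraries of CD45-sorted cells, both from male C57BL/6 animals aged 16 weeks. The tumour library came from colon tumours of ApcMin/+ mice, which carry a mutant allele of the tumour suppressor gene Apc and form intestinal tumours. The wild-type library came from normal colon. The tumour library held 14445 cells and 86724647 UMIs after the authors' filter, with a median of 4397 UMIs and 1509 genes per cell. The wild-type library held 9477 cells and 57159205 UMIs, with a median of 4526 UMIs and 1634 genes. The median mitochondrial share was 2.12% of UMIs in tumour cells and 4.95% in wild-type cells. Each group had 1 library, so there were no replicates, and the 95% intervals in parentheses cover counting error only. The comparisons asked how the immune cells of a colon tumour differ from those of normal colon, above all the regulatory T cells (Treg) and the mature dendritic cells (mregDC) that the series title names. Levels are given as CPM, the UMIs of a gene in the summed cells of a class scaled by their total.

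Apc (ENSMUSG00000005871, GRCm38 chromosome 18, 34220924 to 34322552) was counted at 43.0 CPM (41.6 to 44.4) in the tumour library and 43.7 CPM (42.0 to 45.5) in the wild-type library. The ratio of tumour over wild-type was 0.983 (0.934 to 1.03). A 3′ count does not read the mutated codon, so this level does not check the genotype.

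Neutrophils were the largest class of the tumour library and B cells the largest of the wild-type library. Neutrophils, the short-lived phagocytes of acute inflammation, held 42.8% (41.99 to 43.6) of tumour cells and 0.844% (0.670 to 1.05) of wild-type cells in clusters 3, 4, 6, 7 and 15, a ratio of 50.7 (40.7 to 64.03). Monocytes held 11.9% (11.3 to 12.4) and 0.591% (0.447 to 0.767), a ratio of 20.1 (15.4 to 26.7). Of the 1714 tumour monocytes, 1201 lay in cluster 5, which held 2 wild-type cells. Dendritic cells (DC) held 3.34% (3.06 to 3.65) and 0.570% (0.428 to 0.743), a ratio of 5.87 (4.42 to 7.93). Macrophages of cluster 17, with red cell genes, held 2.13% (1.90 to 2.38) and 0.770% (0.604 to 0.968), a ratio of 2.77 (2.14 to 3.62). Mast cells were 28 tumour cells and 1 wild-type cell. B cells of clusters 0, 1 and 2 held 17.9% (17.3 to 18.6) of tumour cells and 70.2% (69.2 to 71.1) of wild-type cells and were 3.91-fold more frequent in the wild-type library. Plasma cells, the antibody-secreting cells of the gut wall, held 0.242% (0.169 to 0.337) and 4.19% (3.79 to 4.61) and were 17.3-fold more frequent in the wild-type library. Germinal centre B cells of cluster 20, whose leading genes were those of cell division, held 0.942% (0.790 to 1.11) and 1.57% (1.33 to 1.84). T cells and innate lymphocytes together held 11.3% (10.8 to 11.8) and 19.4% (18.6 to 20.2).

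**Figure D1:**
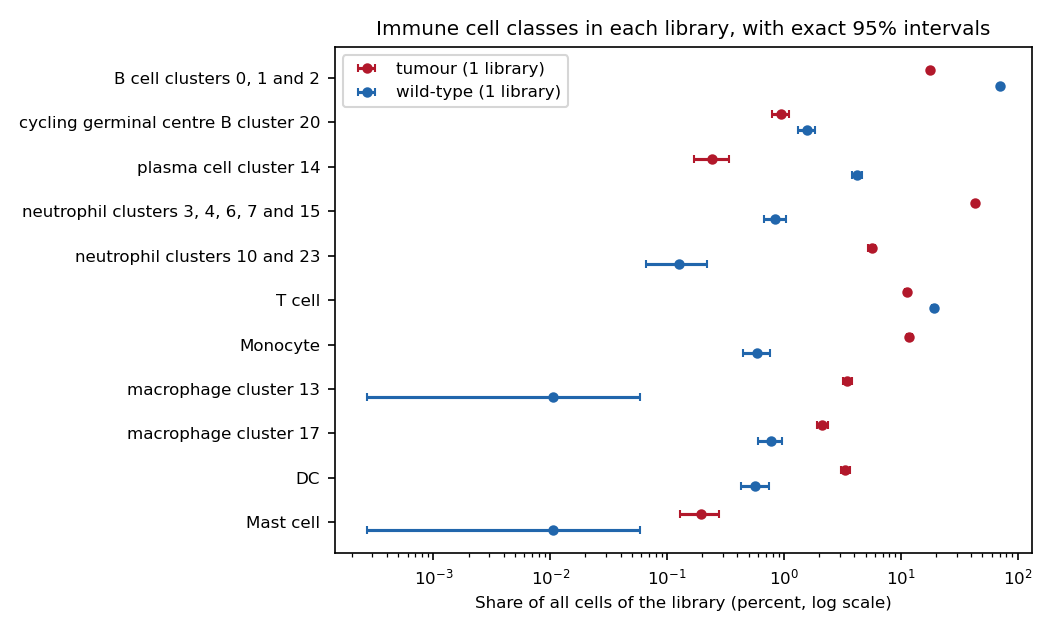
Share of each class among all cells, in percent on a log scale, in the tumour and the wild-type library, with exact 95% intervals as bars. Neutrophils held 42.8% against 0.844% and B cells 17.9% against 70.2%.

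These shares describe CD45-sorted cells after collagenase digestion, not the tissue itself. Tumour and wild-type cells of a class mostly lay in different clusters. Cluster 2 held 2567 of the 2590 tumour B cells, and clusters 0 and 1 held 4002 and 2631 of the 6650 wild-type B cells, so a cluster of 1 library may be that library rather than a cell type. Neutrophil clusters 10 and 23, whose 10 leading genes held more markers of another class, were left out above. They held 5.62% of tumour and 0.127% of wild-type cells. Macrophage cluster 13 was set apart for the same reason and held 3.48% and 0.0106%. Without B cells in the denominator, the ratio of tumour over wild-type was 15.1 for those neutrophils, 5.98 for monocytes, 1.75 for DC and 0.174 for T cells. For macrophages of cluster 17, it turned to 0.824, and for clusters 13 and 17 together it was 2.14, against 7.18 among all cells.

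Within the T cell class, Treg and naive CD8 T cells took larger shares in the tumour library and other CD8 T cells, NK cells and group 2 innate lymphoid cells smaller ones under each way of naming sub-clusters, while the direction for other CD4 and γδ T cells was not kept beyond counting error under each way. Treg-like cells were 14.02% (12.4 to 15.8) of 1633 tumour and 5.23% (4.26 to 6.35) of 1834 wild-type cells of the class, a ratio of 2.68 (2.10 to 3.44). Other CD4 T cells held 13.8% (12.2 to 15.6) and 2.78% (2.08 to 3.64), and γδ T cells 13.8% (12.1 to 15.5) and 2.02% (1.42 to 2.77). Naive CD8 T cells held 14.3% (12.6 to 16.1) and 5.34% (4.36 to 6.47), whereas naive CD4 T cells held 13.7% (12.03 to 15.4) and 12.7% (11.2 to 14.3). Other CD8 T cells were 5.03-fold more frequent in the wild-type library, at 4.41% (3.47 to 5.52) and 22.2% (20.3 to 24.2). NK cells with group 1 innate lymphoid cells held 3.49% (2.65 to 4.499) and 8.72% (7.47 to 10.1). Group 2 innate lymphoid cells, a source of type 2 cytokines, were 13 tumour cells and 195 wild-type cells and 13.4-fold more frequent in the wild-type library. Sub-clusters that mixed T cell with B cell genes held 5.63% (4.57 to 6.86) and 20.7% (18.8 to 22.6), and those that mixed T cell with neutrophil genes 9.49% (8.11 to 11.02) and 0.109% (0.0132 to 0.393). With mixed sub-clusters named by their T cell genes, a way added after the values were seen, other CD4 T cells held 13.8% and 13.5%, a ratio of 1.02 (0.851 to 1.23), since sub-cluster T cell 6 with 197 wild-type cells joined them. With γδ T cells from 200 CPM of Trdc and any Cd8a, also added, they held 18.2% and 18.8%, a ratio of 0.9696 (0.827 to 1.14). This moved 72 tumour and 307 wild-type cells out of the other CD8 T cells, in T cell 0, 19 and 20, with 229, 226 and 582 CPM of Trdc.

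The share of Treg among CD4 T cells was higher in the tumour library by the main names, and its size depended on how sub-clusters were named. Of 678 tumour CD4 T cells, 229 were Treg-like, 33.8% (30.2 to 37.5), and of 380 wild-type CD4 T cells 96 were, 25.3% (20.97 to 29.9), a ratio of 1.34 (1.05 to 1.71). T cell 3 held 227 of the tumour Treg and T cell 14 held 95 of the wild-type Treg. Foxp3 (ENSMUSG00000039521, chromosome X, 7573644 to 7595245), the transcription factor that defines Treg, was counted in 10.7% of tumour and 6.68% of wild-type CD4 T cells after thinning to 1000 UMIs per cell. Without thinning, Foxp3 was counted in 24.3% and 14.7%, at median depths of 4382.5 and 4942 UMIs. In B cells, which lack Foxp3, the background was 0.0394% and 0.0151% thinned, and 0.193% and 0.0752% unthinned at 3643 and 4233 UMIs. With another clustering resolution, the wild-type Treg share was 17.01% of CD4 T cells, and 24.6% without the rule on leading genes, which had left 38 cells with 102 CPM of Foxp3 unnamed, a ratio of 1.36 (1.07 to 1.75). With mixed sub-clusters named by their T cell genes as well, it was 30.8% against 33.5% in the tumour, a ratio of 1.09 (0.8904 to 1.33). At the main resolution, naming the mixed sub-clusters gave 16.6%. With a limit of 80 CPM of Foxp3, the 134 tumour cells of T cell 11 became Treg and the tumour share 53.5%. These ways of naming were added after the values were seen.

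mregDC-like cells were a large part of the tumour DC and rare among wild-type DC. They were 144 of 398 tumour DC, 36.2% (31.5 to 41.1), and 3 of 54 wild-type DC, 5.56% (1.16 to 15.4), plasmacytoid DC left out, a ratio of 6.51 (2.18 to 31.95). Among DC with a named type, they were 144 of 163 in the tumour library and 3 of 52 in the wild-type library, 88.3% and 5.77%. Counted as DC with UMIs of 2 or more of Ccr7, Fscn1, Lamp3 and Ccl22, they were 48.7% of the tumour and 7.41% of the wild-type DC. This count also took 53 of the 136 tumour cells of sub-cluster DC 0, 38.97%, but 2 of the 118 remaining other tumour DC and 3 of 1714 tumour monocytes. Fscn1 (ENSMUSG00000029581, chromosome 5, 142960343 to 142973185), which bundles actin in mature DC, gave the cells their name here. Ccr7 (ENSMUSG00000037944, chromosome 11, 99144196 to 99155077), the receptor that guides DC into lymphatics, was at 2373 CPM in the tumour mregDC-like cells and 320.0 CPM in the other tumour DC. Fscn1 was at 1703 against 56.6 CPM and Ccl22 (ENSMUSG00000031779, chromosome 8, 94745590 to 94751699), which attracts Treg through Ccr4, 3.71-fold (3.496 to 3.95) higher. Cd274 (ENSMUSG00000016496, chromosome 19, 29367455 to 29388095), which encodes PD-L1, was at 471 against 196 CPM. These 4 genes mark the class, and Lamp3 had 0 UMIs in every class. The mregDC-like cells came from sub-clusters DC 1 and DC 4.

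Conventional type 1 and type 2 DC made up most of the wild-type DC. Type 1 DC, which carry Xcr1, held 4.77% (2.90 to 7.35) of tumour and 29.6% (17.98 to 43.6) of wild-type DC. Type 2 DC were 33 wild-type cells, 61.1% (46.9 to 74.1), and no tumour sub-cluster met their limit. Another 235 tumour DC and 2 wild-type DC lay in sub-clusters that the limits left unnamed. Of these, DC 0 held 136 tumour cells, led with Tgm2, Clec4n, Il1b and Ccl17, and had a neutrophil marker score of 1.82 and 4938 CPM of S100a8. DC 3 held 73 tumour cells and a monocyte marker score of 0.976, and its Cd209a, a marker of type 2 DC, was at 652 CPM, against 755 CPM in the named type 2 DC. Plasmacytoid DC, the interferon-producing DC marked by Siglech, were 85 of 483 tumour DC, 17.6% (14.3 to 21.3), and 0 of 54 wild-type DC, which allows up to 5.56%.

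Within the tumour library, the comparison of mregDC-like cells with the other DC asked what sets them apart beyond their markers. The other DC were 254 cells, 136 of them of sub-cluster DC 0 with its neutrophil genes and 73 of DC 3 with its monocyte genes, so some values are also given without DC 0, an alternative added after the values were seen. The mregDC-like cells had less MHC class II and more MHC class I, Il12b and Il15 than the other DC. H2-Ab1, a chain of MHC class II, was 2.69-fold (2.60 to 2.78) lower, H2-Aa 1.85-fold (1.79 to 1.90) lower and Cd74, the invariant chain, 1.92-fold (1.88 to 1.95) lower. Of 15 MHC class II genes, 12 were lower and 0 higher, with a median log2 ratio of -0.91, and of 14 MHC class I genes, 9 were higher and 2 lower, with a median of 0.91. H2-K1 was 2.31-fold (2.21 to 2.42) and the immunoproteasome gene Psmb9 2.04-fold (1.86 to 2.23) higher. Without DC 0, these medians were −1.17 and 0.78. Among costimulatory genes, 6 of 11 were higher and 1 lower, with a median of 0.87 that became 2.43 without DC 0. Il12b, a chain of interleukin-12, was at 49.4 against 0.682 CPM, 72.4-fold (19.4 to 608) higher on 2 counts in the other DC. Il15 was 5.34-fold (3.12 to 9.51) and Cd40 2.09-fold (1.70 to 2.56) higher, while Cd80 had a ratio of 0.981 (0.838 to 1.15) and Cd86 of 1.12 (0.978 to 1.29). Pdcd1lg2, which encodes PD-L2, was 1.84-fold (1.57 to 2.15) higher, and Ccl17, another Ccr4 ligand, 1.499-fold (1.41 to 1.59) lower. Without DC 0, Ccl17 was higher instead, with a log2 ratio of 3.54, and Cd80 and Cd86 had 3.20 and 1.54.

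The immune regulation genes of mregDC-like cells split, with 5 of 11 higher and 6 lower and a median of -1.27 that turned to 0.43 without DC 0. Aldh1a2, which makes retinoic acid, was 8.51-fold (4.24 to 18.9) and Ebi3 2.72-fold (1.96 to 3.79) higher, while Havcr2 was 8.81-fold (5.47 to 15.1) and Vsir 6.84-fold (4.23 to 11.8) lower. Among chemokines other than Ccl22, Ccl5 was 12.4-fold (11.2 to 13.8) higher and Cxcl10 9.73-fold (6.27 to 15.9) lower, with 2 of 15 higher and 9 lower and a median of -1.73. Without DC 0, the chemokine median turned to 2.34 and Cxcl10 to 4.01. Type I interferon response genes were lower in 17 of 21, with Irf7 5.44-fold (3.38 to 9.23) lower. Interferon gamma response genes were higher in 7 of 15 and lower in 4. The receptors of Treg biology Il2ra and Tnfrsf4 were 19.9-fold (12.4 to 33.8) and 34.9-fold (19.6 to 68.4) higher. The 3 wild-type mregDC-like cells were too few to compare.

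**Figure D2:**
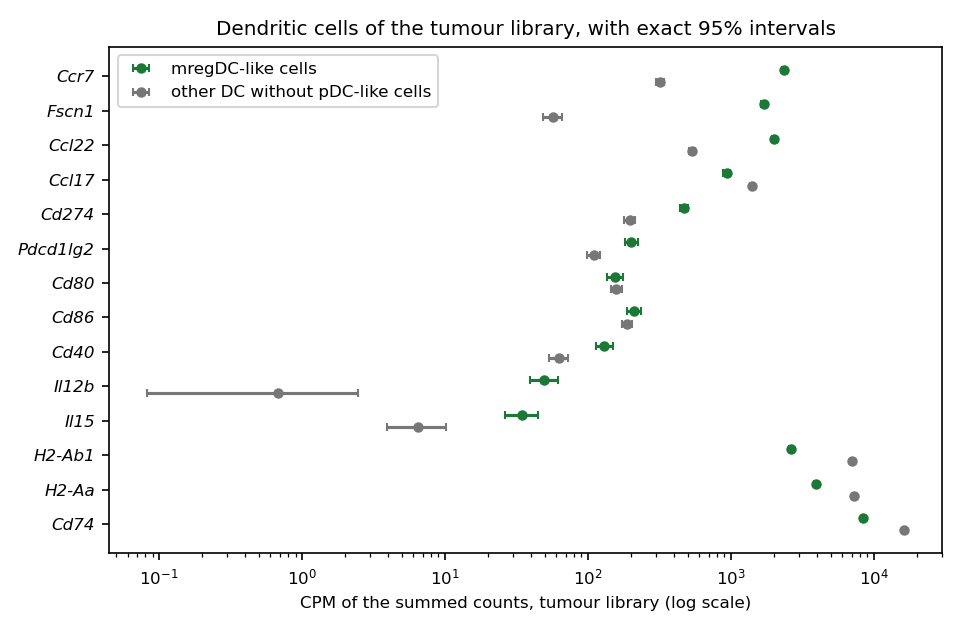
Level of 14 genes in the mregDC-like cells and the other DC of the tumour library, in CPM on a log scale, with exact 95% intervals as bars. Il12b was at 49.4 against 0.682 CPM, and MHC class II genes were lower in the mregDC-like cells.

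DC of cluster 18 had more Ccl22, Ccl17 and PD-L2 and more interferon response genes in the tumour library. Ccl22 was 479.7 against 8.99 CPM in tumour and wild-type cells, 53.4-fold (24.5 to 146) higher, and Ccl17 (ENSMUSG00000031780, chromosome 8, 94810453 to 94812036) 1351 against 139 CPM, 9.70-fold (7.90 to 12.05) higher. Pdcd1lg2 was 14.2-fold (6.01 to 44.003) higher, Il1rn, the interleukin-1 receptor antagonist, 12.4-fold (7.23 to 23.5) and Il7r 13.5-fold (7.69 to 26.3). Ifitm1 was 31.8-fold (25.8 to 39.5) higher, and Zmynd15, Slc7a11, Ly6c2 and Ramp3 were also among the 10 highest. Ifitm1 was at least 2-fold higher in the tumour in all 14 classes compared, so its rise is not particular to DC. In wild-type cells, Wnt11 was 40.3-fold (21.6 to 83.2) higher, Cd36, a lipid scavenger receptor, 12.4-fold (6.99 to 22.96) and Cd81 12.1-fold (8.11 to 18.5). Hspa1b (ENSMUSG00000090877, chromosome 17, 34956436 to 34959238), a heat shock gene, was 32.7-fold (25.02 to 43.3) higher in wild-type cells, with Hspa1a, Ear2, Atf3, Rasgef1b, Tent5c and Nfkbiz. The compared cells were 257 tumour and 53 wild-type cells. Of these, 224 tumour cells were unnamed, while 33 wild-type cells were type 2 DC and 16 type 1 DC, so this ratio also compares DC types.

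In those DC, maturation genes had a median log2 ratio of 1.51 (1.03 to 1.77), with 10 of 16 higher and 1 lower, and 0.56 without members whose level was under 10% of that in another class. Cd63 was 17.1-fold (6.59 to 62.99) higher and the adhesion gene Icam1 2.27-fold (1.83 to 2.80) higher in wild-type cells. Regulatory genes had a median of 1.42 (1.02 to 1.83), with 9 of 15 higher and 0 lower. Costimulatory genes showed no common direction, at 0.09 (-0.41 to 0.49), since Cd80 was 2.77-fold (1.99 to 3.96) higher in tumour cells and Cd83 3.52-fold (3.14 to 3.94) and Tnfsf9 4.07-fold (3.13 to 5.28) higher in wild-type cells. MHC class II genes stayed within 1.5-fold in 9 of 15, with Ctss 1.63-fold (1.48 to 1.81) higher in tumour cells and H2-Ob 2.29-fold (1.80 to 2.90) in wild-type cells. Interferon gamma response genes had a median of 1.33 (1.10 to 1.68), with Irgm1 6.42-fold (2.89 to 17.8) higher and Irf8 2.25-fold (2.02 to 2.498) higher in wild-type cells. Type I interferon response genes were higher in 20 of 20, with a median of 1.79 (1.64 to 2.51).

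Treg of the tumour, mostly T cell 3, had more Il1r2, Fabp5, Ly6a and Penk and less Il10 than Treg of normal colon, mostly T cell 14. Other Treg names were not tested. Il1r2, a decoy receptor for interleukin-1, was 362 against 24.2 CPM, 14.99-fold (8.06 to 31.5) higher, and Fabp5, a fatty acid carrier, 1105 against 102 CPM, 10.9-fold (8.001 to 15.2) higher. Penk, which encodes proenkephalin, was 5.42-fold (3.91 to 7.71) higher, Ly6a 5.10-fold (4.35 to 6.01), Tff1 11.5-fold (7.82 to 17.8) and the potassium channel gene Kcna4 42.02-fold (7.38 to 1675). Ermn, Nrn1, Ifi47 and Pdgfb were also among the 10 highest. Il10 (ENSMUSG00000016529, chromosome 1, 131019845 to 131024974), the suppressive cytokine, was 109 against 1214 CPM, 11.1-fold (9.05 to 13.7) higher in wild-type Treg. Cxcl10 was 16.9-fold (9.61 to 32.2), Cd83 12.7-fold (8.74 to 18.9), Lmna 8.76-fold (6.53 to 11.9) and Klf4 22.98-fold (11.5 to 52.04) higher in wild-type Treg. Hspa1b was 127-fold (34.4 to 1066) higher there and Hspa1a at least 47.9-fold, at 138 CPM against 0 tumour counts, with Atf3, Vps37b and Ets2. Foxp3 was 320.2 against 229.8 CPM, 1.39-fold (1.11 to 1.77) higher in tumour Treg, Il2ra, the high-affinity receptor chain for interleukin-2, 1.83-fold (1.52 to 2.20) higher and Ctla4 at 1110.3 against 2276 CPM, 2.05-fold (1.88 to 2.24) higher in wild-type Treg. Ccr8 had a ratio of 1.90 (0.712 to 6.39), Ccr4, the receptor of Ccl17 and Ccl22, of 0.717 (0.496 to 1.05) and Icos was 1.29-fold (1.15 to 1.44) higher in wild-type Treg.

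The Treg effector genes did not move together. Of 31 measured, 12 were higher in tumour Treg, 6 lower and 13 within 1.5-fold, with a median of 0.14 (-0.07 to 0.39). Ikzf4 was 4.41-fold (2.60 to 8.06) and Tnfrsf9 2.85-fold (2.46 to 3.31) higher. Areg was 2.29-fold (1.995 to 2.62) higher in wild-type Treg. Exhaustion and checkpoint genes had a median of -0.65 (-1.07 to -0.36), where Havcr2, which encodes TIM-3, was 2.32-fold (1.61 to 3.44) higher in tumour Treg, and the early genes Nr4a1 and Nr4a3 were 7.53-fold (5.79 to 9.90) and 5.04-fold (3.66 to 7.02) higher in wild-type Treg. Interferon genes were higher in tumour Treg: type I response genes in 10 of 12, with a median of 1.13 (0.87 to 1.51), and interferon gamma response genes in 10 of 16, with a median of 1.06 (0.69 to 1.28). Iigp1 was 6.51-fold (3.06 to 16.6) and Zbp1 4.66-fold (2.27 to 11.1) higher. Glycolysis and hypoxia genes were higher in 16 of 23 and lower in 0, with a median of 0.88 (0.75 to 1.15) and Tpi1 3.34-fold (2.28 to 5.06) higher. Gut homing genes were higher in 8 of 16, with Ccr6 2.87-fold (1.72 to 5.08) and a median of 0.57 (0.40 to 0.80). Klf2 was 2.33-fold (1.96 to 2.78) higher in wild-type Treg, and naive and central memory genes had a median of 0.80 (0.59 to 1.13). Lists made for myeloid cells were higher in tumour Treg too, at 2.37 (1.88 to 2.78) for tumour-associated macrophage and 2.21 (1.71 to 3.06) for inflammatory genes. Chemokines had 1.09 (0.77 to 1.65). In naive CD4 T cells these lists had 3.27, 4.75 and 5.15, so their rise is not particular to Treg.

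Against the other CD4 T cells of the same library, Treg carried more Areg, Il1rl1, Il10 and Gzmb in both tissues. Naive CD4 T cells were 223 of the 449 other CD4 T cells in the tumour and 233 of 284 in normal colon, so the folds of the 2 libraries have different references and are not compared with each other. Areg was 94.2-fold (50.8 to 198) higher in tumour Treg and 34.2-fold (24.9 to 47.9) in wild-type Treg. Il1rl1, the receptor of interleukin-33, was 51.7-fold (24.6 to 131) and 338-fold (59.3 to 13509) higher, the second on 1 count in the other CD4 T cells. Il10 was 7.70-fold (5.14 to 11.9) higher in the tumour and 201-fold (105 to 442) in normal colon. Gzmb, which encodes granzyme B, was 6.87-fold (5.87 to 8.07) and 350.2-fold (136 to 1292) higher. Itgae, the integrin that binds epithelium, was 12.7-fold (9.41 to 17.4) and 43.9-fold (17.8 to 140.1) higher. Effector genes outside the markers were higher in 21 of 21 in the tumour and in 17 of 17 in normal colon, with medians of 2.78 and 4.77. Gut homing genes had medians of 1.39 and 2.61, and type 2 genes of 1.70 and 5.09. Naive genes were lower in 11 of 12 in each library. Il17a was 15.6-fold (9.88 to 26.03) lower and Il17f 119-fold (40.5 to 577) lower in tumour Treg than in the other tumour CD4 T cells, the second on 3 counts. Of the other tumour CD4 T cells, 134 lay in sub-cluster T cell 11, whose Foxp3 was at 83.4 CPM and whose 10 leading genes held 2 Treg markers. Without it, in an alternative added after the values were seen, the tumour medians were 2.57 for effector and 4.06 for type 2 genes and the log2 ratio of Gzmb was 2.41. Scaling by a median-of-ratios factor would lower every log2 ratio of this comparison by 0.31 in the tumour and 0.41 in normal colon.

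The other CD4 T cells of the tumour carried type 17 cytokines that the 51 wild-type cells lacked. Il17a (ENSMUSG00000025929, chromosome 1, 20730905 to 20734496) was at 537 CPM, Il17f at 651 CPM and Il22 at 529 CPM in 226 tumour cells, with 0 counts of each in 51 wild-type cells. These were at least 52.3, 63.3 and 51.5-fold higher. Ccl20, the ligand of Ccr6, was at 167 CPM against 0 counts, at least 16.2-fold higher. Type 17 genes were higher in 8 of 13 and lower in 0, with a median of 1.56 (1.08 to 2.27) that stood at 4.66 for members with 100 UMIs or more. Rora, a regulator of type 17 cells, was 343 against 377 CPM. Interferon gamma response genes were higher in 12 of 14, with Serpina3g 9.03-fold (2.41 to 76.04) higher. Areg was 15.7-fold (7.72 to 35.2) higher in wild-type cells, while Gata3 was 87.2 against 71.99 CPM and the type 2 genes had a median of 0.25 (-0.44 to 0.82). Hspa1b was 84.1-fold (34.9 to 264), Hspa1a 27.9-fold (13.8 to 63.9), Nr4a2 23.6-fold (9.84 to 68.5) and Dusp10 12.1-fold (7.85 to 19.03) higher in wild-type cells. The class was T cell 11 and 15 in the tumour and T cell 23 in normal colon. T cell 11 and 23 had Treg markers in their leading genes. Mixed T cell 6, with 197 wild-type cells, was not tested.

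γδ T cells of the tumour carried Il17a, while their granzyme and Il23r contrasts depended on the limits that name the class. Gzma, which encodes granzyme A, was at 2259 CPM against 0 counts, at least 170.1-fold higher, Gzmb 101-fold (39.4 to 371) and Gzmc at least 23.97-fold higher. Il17a was at 3732 against 128 CPM, 29.1-fold (20.2 to 43.5) higher, and Il22 at least 16.2-fold higher. The chemokine gene Ccl1 was at 725 CPM against 0 counts and Spp1 at least 55.8-fold higher. Klrk1, the activating receptor NKG2D, was 25.1-fold (17.9 to 35.8) higher in wild-type cells and Il23r 7.86-fold (4.22 to 14.7). Cytotoxicity genes were higher in 13 of 17, with a median of 3.11 (2.58 to 3.77), chemokines in 7 of 8, with a median of 4.31 (3.40 to 4.36), and type 17 genes in 7 of 15, with a median of 0.26 (-0.14 to 1.11). Chemokines turned to −0.15 with every member of 1 UMI or more. In wild-type cells, Hspa1a was at least 206-fold, Hspa1b 266-fold (112 to 830.4), Lmna 149-fold (48.6 to 741) and Atf3 72.8-fold (36.7 to 164) higher. With γδ T cells from 200 CPM of Trdc and any level of Cd8a, a setting added after the values were seen, sub-clusters T cell 0 and 20 with 306 wild-type cells joined the class, and Gzma was at 1838 CPM in the tumour and 2030 CPM in normal colon, a ratio of 0.906 (0.866 to 0.947). In that setting, Gzmb was 1.92-fold (1.80 to 2.05), Gzmc 18.05-fold (12.3 to 27.4) and Il17a 185-fold (131 to 273) higher in the tumour, and the cytotoxicity median was 0.47. Klrk1 had a ratio of tumour over wild-type of 0.388 (0.329 to 0.458) there, and Il23r one of 0.833 (0.448 to 1.54), whose interval held 1. The class as named was 225 cells of T cell 4 in the tumour and 37 of T cell 25 in normal colon. A median-of-ratios factor would add 0.20 to each log2 ratio.

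The sub-clusters named other CD8 T cells had more Ncr1, Cxcr6 and Ltb in the tumour and more Gzma and Ifng in normal colon. Ncr1, an activating receptor of NK cells, was 176 against 27.98 CPM, 6.28-fold (4.44 to 8.90) higher, Cxcr6 4.14-fold (3.05 to 5.59) and Ltb, which encodes lymphotoxin beta, 4.10-fold (3.58 to 4.70). Penk was at 120.4 CPM against 0 counts, at least 94.6-fold higher, with Sema6d, Nrgn, Ddit4 and Klrb1b. Gzma was 190.2 against 1664 CPM, 8.75-fold (7.01 to 11.1) higher in wild-type cells, and Ifng, the type 1 effector cytokine, 7.22 against 124 CPM, 17.2-fold (5.83 to 83.9). Nr4a2 was 17.9-fold (11.2 to 30.9), Tnfaip3 11.6-fold (8.70 to 15.8) and Irs2 30.1-fold (10.2 to 147) higher in wild-type cells, with Hspa1b, Hspa1a, Fosb, Vps37b, Nr4a1 and Nr4a3. Cytotoxicity genes split into 6 higher, 8 lower and 4 within 1.5-fold, with a median of 0.07 (-0.28 to 0.27), and Xcl1 was 2.02-fold (1.88 to 2.17) higher in tumour cells. Exhaustion genes had a median of -0.42 (-0.78 to 0.02), with Cd244a 2.34-fold (1.84 to 2.95) and Cd160 1.62-fold (1.40 to 1.87) higher in tumour cells. Type 17 genes were higher in 5 of 8 and lower in 0, with Tmem176a 5.68-fold (3.82 to 8.44) and Tmem176b 4.12-fold (2.74 to 6.15). The 72 tumour cells lay mostly in sub-cluster T cell 19 and the 407 wild-type cells in T cell 0, 12 and 20. T cell 0 and 19 had γδ receptor genes among their 10 leading genes, so the class also holds γδ T cells, and a median-of-ratios factor would take 0.20 from each log2 ratio.

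Naive CD8 and naive CD4 T cells had more stress genes in normal colon. In naive CD8 T cells, Hspa1b was 1.44 against 342 CPM, 238-fold (65.1 to 1978) higher in wild-type cells, Jun 12.1-fold (8.91 to 16.7), Nr4a2 49.4-fold (18.6 to 185) and Tnfaip3, an inhibitor of NF-kappaB, 10.9-fold (8.07 to 14.9), with Hspa1a, Vps37b, Fosb, Klf4, Nr4a3 and Dnajb9. Stress genes were lower in 18 of 22 in tumour naive CD8 T cells, with a median of -1.82 (-1.91 to -1.65), and in 19 of 22 in naive CD4 T cells, with a median of -2.08 (-2.21 to -1.91). Higher in tumour naive CD8 T cells were Kcnq1ot1 by 3.05-fold (2.40 to 3.92), Trim12c by 4.21-fold (2.11 to 9.51), Pou2f2 by 3.94-fold (2.26 to 7.43) and Cd52 by 2.02-fold (1.86 to 2.19), with Sept1, Traf3ip3, Arl4c, Crtc3, Pglyrp2 and Ms4a4b. Naive genes barely differed, with medians of 0.11 (-0.08 to 0.22) and -0.04 (-0.14 to 0.05) in CD8 and CD4 cells and Ccr7 1.97-fold (1.71 to 2.28) and 1.78-fold (1.55 to 2.05) higher in wild-type cells. In naive CD4 T cells, Ly6a was 4.60-fold (3.57 to 5.99) higher in the tumour, with Zfp950, Ptprcap and Kcnq1ot1, and MHC class I genes were higher in 5 of 14 and lower in 0, with a median of 0.43 (0.31 to 0.61) and Psmb8 2.19-fold (1.88 to 2.55). Hspa1b had 0 counts in tumour naive CD4 T cells against 741 CPM, at least 256-fold higher, and Hspa1a, Nr4a3 and Nr4a2 followed. Type I interferon response genes were higher in 9 of 16 in naive CD8 T cells, with a median of 0.75 (0.63 to 1.37). Lists made for other cell types had medians further from 0 in these cells: 4.72 (3.45 to 5.24) and 4.75 (4.09 to 6.13) for inflammatory genes in CD8 and CD4 cells, 3.22 (2.37 to 3.54) and 5.15 (4.05 to 5.36) for chemokines, 2.49 (2.03 to 2.77) and 3.27 (2.77 to 3.58) for tumour-associated macrophage genes and -2.59 (-2.99 to -2.17) and -2.17 (-2.96 to -1.58) for immunoglobulin genes. The naive genes of CD4 cells stood at −0.18 with a median-of-ratios factor, which takes 0.14 from each log2 ratio.

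NK cells and group 1 innate lymphoid cells had more Eomes and Gzma in the tumour and more Ifng in normal colon. Eomes, a transcription factor of NK cells, was 16.3-fold (10.1 to 27.4) higher in the tumour, Klra4 17.2-fold (12.1 to 25.02) and Sh2d1a 16.4-fold (8.500 to 34.8). Gzma was 7.06-fold (6.35 to 7.86) and Ccl5 3.79-fold (3.58 to 4.0004) higher. In wild-type cells, Il22 was at 505 CPM against 0 counts, at least 47.4-fold higher, Ifng 10.4-fold (6.51 to 17.6) and Gzmc 9.62-fold (4.04 to 30.04), with Hspa1b, Gadd45b and Rgcc. Of the 467 wild-type Il22 UMIs, 459 came from 12 cells that the other clustering resolution set apart and left unnamed, with group 3 innate lymphoid markers highest, so Il22 is no gene of the NK cells here. Cytotoxicity genes were higher in 6 and lower in 9 of 18, with a median of -0.46 (-0.60 to -0.11), naive genes higher in 6 of 9, and type 2 genes had a median of -1.74 (-2.19 to -1.22) over 3 measured genes. The class was 57 tumour cells, mostly of sub-cluster T cell 22, and 160 wild-type cells, mostly of T cell 10, so the ratio may compare 2 kinds of cell, and a median-of-ratios factor would take 0.14 from each log2 ratio.

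Macrophages of cluster 17 had more Arg1, Spp1, Mmp12 and Mmp9 in the tumour and more Il10, Cd163 and MHC class II in normal colon. Arg1 (ENSMUSG00000019987, chromosome 10, 24915221 to 24927484), which depletes arginine, was at 570.0 CPM against 0 counts, at least 126-fold higher. Spp1, which encodes osteopontin, was 353 against 4.51 CPM, 78.2-fold (26.6 to 380.4) higher, and the proteases Mmp12 and Mmp9 were 24.4-fold (16.6 to 37.5) and 18.3-fold (11.2 to 32.2) higher. Il10 was 91.4-fold (24.4 to 769) higher in wild-type macrophages, Cd163, the haemoglobin scavenger receptor, 22.2-fold (7.95 to 86.1), Cd83 30.4-fold (24.2 to 38.7), Cd209a 76.2-fold (20.2 to 644) and Retnla 15.9-fold (13.9 to 18.1). Tumour-associated macrophage genes were higher in 13 and lower in 7 of 22, with a median of 0.89 (0.76 to 1.07) and Lpl, a lipase, 5.77-fold (4.99 to 6.68) higher in wild-type cells. Resident macrophage genes had a median of -0.43 (-0.58 to -0.15), which turned to 0.18 for members with 100 UMIs or more, and the lipid carrier Apoe was 2.71-fold (2.64 to 2.78) higher in the tumour. MHC class II genes were lower in 10 of 15, with a median of -0.81 (-0.94 to -0.59) and H2-Eb1 2.39-fold (2.30 to 2.47) higher in wild-type cells. Glycolysis and hypoxia genes were higher in 18 of 24, with a median of 1.44 (1.29 to 1.64), Slc2a3 6.83-fold (3.03 to 19.03) and Mif 6.22-fold (5.02 to 7.79).

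Red cell and platelet transcripts were higher in tumour macrophages and in other tumour classes. Hba-a1, a haemoglobin chain, was at 7341 CPM in tumour cells of cluster 17 against 0 counts, Alas2, the enzyme of haem synthesis in red cells, at 60.4 CPM and Ppbp, a platelet chemokine, 26.6-fold (8.99 to 130.3) higher, and the list had a median of 9.51 (9.47 to 9.55). Its median was 6.69 (6.33 to 7.36) in B cells and 1.40 (1.17 to 1.66) in γδ T cells. Also among the 10 highest were Ube2c, Syngr1, Mfge8 and Ass1 in the tumour and Gdf15, Cxcl1, Tppp3, Gadd45b, Pdlim1 and Clec4b1 in normal colon. Ctss and Pf4 had log2 ratios of 1.06 and 0.58 but were lower by the means of the authors' normalized values. The 3 stromal genes measured had a median of 2.22 (1.22 to 3.56), or −0.0258 with every member of 1 UMI or more. The median was 3544 UMIs in the 308 tumour cells, with 103 under 1000, and 10690 in the 73 wild-type cells, with 8. Cluster 17 scored 4.12 for erythroid and 3.83 for macrophage markers. A median-of-ratios factor would add 0.19 to each log2 ratio.

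Monocytes of cluster 11 had more interferon response genes in the tumour and more MHC class II and Thbs1 in normal colon. All 21 type I interferon response genes measured were higher in the tumour, with a median of 1.40 (1.24 to 1.76). Ifit3 was 57.4 against 9.78 CPM, 5.87-fold (2.66 to 16.1) higher, Isg15 5.12-fold (3.52 to 7.74) and Oasl2 4.58-fold (3.08 to 7.11). Lrg1 was 13.1-fold (6.01 to 35.96) higher, Hdc 5.25-fold (3.70 to 7.71) and Egr1 4.33-fold (3.48 to 5.45). Slfn1, Pglyrp1, Zfp217, Rtp4 and Tmcc1 completed the 10 highest. Lrg1, Pglyrp1 and Hdc are leading genes of neutrophil clusters 3, 4 and 6, so neutrophil RNA is not excluded. Thbs1 was 342 against 2366 CPM, 6.92-fold (6.45 to 7.43) higher in wild-type monocytes. Ccl24 was 15.4-fold (10.9 to 22.2), Cd83 18.3-fold (14.2 to 23.8) and Hbegf 35.5-fold (16.2 to 88.7) higher there. Rasgef1b, Ifrd1, Pim3, Rab7b, Nr4a3, Irs2 and Odc1 were also among the 10 highest there. MHC class II genes were lower in 9 and higher in 1 of 15, with a median of -0.61 (-0.77 to -0.50) and H2-Eb1 2.40-fold (2.11 to 2.73) higher in wild-type monocytes. Inflammatory genes were lower in 8 and higher in 4 of 16, with a median of -0.60 (-0.67 to -0.06). The sums held 513 tumour and 54 wild-type cells.

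Neutrophils of cluster 7 had more glycolysis and hypoxia genes in the tumour. Those genes were higher in 22 of 24, with a median of 2.25 (1.90 to 2.46), Ankrd37 18.2-fold (3.25 to 721) higher on 1 count in wild-type cells and P4ha1, a collagen hydroxylase induced by low oxygen, 13.2-fold (3.64 to 109) on 2 counts. Vegfa was 4.77-fold (3.69 to 6.10) higher in wild-type neutrophils and Il23a, a chain of interleukin-23, 9.09-fold (6.90 to 11.9). Spp1 was 57.8-fold (19.8 to 280.3) higher in tumour neutrophils, Cxcl3, a neutrophil attractant, 3948 against 214 CPM, 18.4-fold (13.3 to 26.3), Cstdc4 18.3-fold (12.05 to 29.1) and Esd 34.3-fold (9.47 to 283). Lsmem1 was 506-fold (167 to 2511), Cd83 37.2-fold (20.6 to 69.1), Slc38a1 27.7-fold (19.8 to 39.1) and Impact 28.9-fold (19.5 to 43.2) higher in wild-type cells. Inflammatory genes had a median of -0.52 (-0.68 to -0.36), which was −0.00616 with a median-of-ratios factor, and chemokines were higher in 5 and lower in 6 of 13, with a median of -0.54 (-0.86 to -0.03) that turned to 1.06 for members with 100 UMIs or more. That factor would add 0.51 to each log2 ratio of these 1018 tumour and 60 wild-type cells.

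B cells of clusters 0, 1 and 2 had more Ltb and interferon response genes in the tumour and more Cd83 and Cd86 in normal colon. Ltb was 992 against 198 CPM, 5.01-fold (4.86 to 5.18) higher, Gimap7 4.22-fold (3.90 to 4.58), Ly6a 3.55-fold (3.39 to 3.72) and Trim34a 3.52-fold (3.19 to 3.89). All 21 type I interferon response genes measured were higher, with a median of 1.57 (1.39 to 1.97). Cd83 was 204 against 971 CPM, 4.77-fold (4.56 to 4.99) higher in wild-type B cells, and Cd86, a ligand of CD28, 3.85-fold (3.54 to 4.21), while Cd40 was 1.98-fold (1.79 to 2.19) and Icosl 1.69-fold (1.56 to 1.83) higher in tumour B cells. Costimulatory genes had a median of 1.16 (0.85 to 1.32), with 7 of 10 higher. MHC class II genes stayed within 1.5-fold in 13 of 15, with a median of 0.12 (0.10 to 0.16) that turned to −0.12 with a median-of-ratios factor, which takes 0.24 from each log2 ratio. Irs2 was 36.7-fold (32.2 to 41.97), Hspa1b 139-fold (92.3 to 219), Hspa1a 127-fold (75.6 to 232) and the clock gene Ciart 29.1-fold (18.3 to 49.2) higher in wild-type B cells.

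Germinal centre B cells of cluster 20 had more division genes in the tumour. Proliferation genes were higher in 9 of 23 and lower in 0, with a median of 0.53 (0.41 to 0.59), Tk1 2.001-fold (1.500 to 2.68) and Nusap1 1.92-fold (1.54 to 2.41). The histone gene Hist1h1b was 4.79-fold (4.18 to 5.51) higher, Ly6a 4.46-fold (3.56 to 5.63), Kcnq1ot1 2.93-fold (2.54 to 3.38) and Cr2, a complement receptor, 3.13-fold (2.54 to 3.87). Irs2 was 12.99-fold (6.88 to 27.6), Lncpint 7.87-fold (3.95 to 17.8), Rhob 6.16-fold (3.58 to 11.4) and Klf2 4.54-fold (3.58 to 5.82) higher in wild-type cells. MHC class II genes had a median of 0.31 (0.19 to 0.36), with Ctss 1.86-fold (1.55 to 2.23) and Ifi30 1.73-fold (1.53 to 1.96) higher in the tumour.

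Plasma cells of cluster 14 made different immunoglobulins in the 2 libraries. Ighm, the heavy chain of IgM, was 23858 against 441 CPM, 54.1-fold (52.4 to 55.9) higher in the tumour, and Ighg2c was at 2406 CPM against 0 counts, at least 8408-fold higher. The light chains Iglc3 and Iglc2 were 26.2-fold (23.96 to 28.6) and 3.85-fold (3.65 to 4.06) higher in wild-type cells, and the immunoglobulin genes had a median of 0.38 (0.03 to 0.59), with 4 higher and 4 lower of 11. Apoe was 242-fold (211 to 279) higher in the tumour, Slpi, an inhibitor of neutrophil proteases, 12.3-fold (11.97 to 12.7), Prg2 7.79-fold (6.85 to 8.84) and Cd79a, a chain of the B cell receptor, 3.51-fold (3.29 to 3.75). Vim was 21.8-fold (15.2 to 32.3), Ahnak 34.6-fold (14.8 to 107), Crip1 16.4-fold (13.4 to 20.3) and Lmna 26.3-fold (12.1 to 71.8) higher in wild-type cells. MHC class I genes were lower in 10 of 14, with a median of -0.84 (-1.05 to -0.67) and H2-D1 2.64-fold (2.32 to 3.03) higher in wild-type cells. Wnt target genes had a median of -1.17 (-1.48 to -0.35) over 5 genes, which turned to 0.22 when every member with 1 UMI or more was kept, with Cd44 2.33-fold (1.85 to 2.98) higher in wild-type cells and Ifitm3 3.79-fold (2.86 to 4.95) in the tumour. The tumour library held 35 plasma cells and the wild-type library 397, and a median-of-ratios factor would add 0.35 to each log2 ratio and bring the immunoglobulin median to 0.73.

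Across the 14 classes compared, the median of the stress genes was below 0 and that of the type I interferon response genes above 0. The median of the dissociation stress genes lay below 0 in all 14, from -2.08 in naive CD4 T cells to -0.32 in monocytes. Of 4460 genes measured in every class, 21 were at least 2-fold higher in wild-type cells in 13 or 14 of the 14. Hspa1b had a median log2 ratio of −5.79 over the classes, Vps37b −3.27, Irs2 −3.11 and Tnfaip3 −2.73. Another 6 genes were at least 2-fold higher in tumour cells in 13 or 14 classes, among them the neutrophil genes S100a9, S100a8 (ENSMUSG00000056054, chromosome 3, 90668978 to 90670035), Retnlg and G0s2, with medians of 8.37, 7.88, 6.09 and 6.24. S100a8, S100a9 and Retnlg were set apart in lymphoid cells as possible free RNA, and immunoglobulin genes, which plasma cells release, had medians of -2.08 in Treg and -2.80 in DC. Type I interferon response genes had medians above 0 in all 14 classes, from 0.24 in macrophages to 1.79 in DC, with intervals that held 0 in NK cells, 0.27 (-0.61 to 0.60), and plasma cells, 0.43 (-0.48 to 0.74). The median turned to −0.24 in macrophages without members under 10% of their highest class, a setting added after the values were seen, and to −0.19 in γδ T cells when every member with 1 UMI or more was kept. Interferon gamma response genes were not shared in this way, with medians of -1.74 (-1.995 to -1.04) in plasma cells, -0.27 (-0.49 to 0.12) in macrophages and -0.08 (-0.73 to 0.15) in neutrophils. Fewer than 3 epithelial genes were measured in any class.

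**Figure D3:**
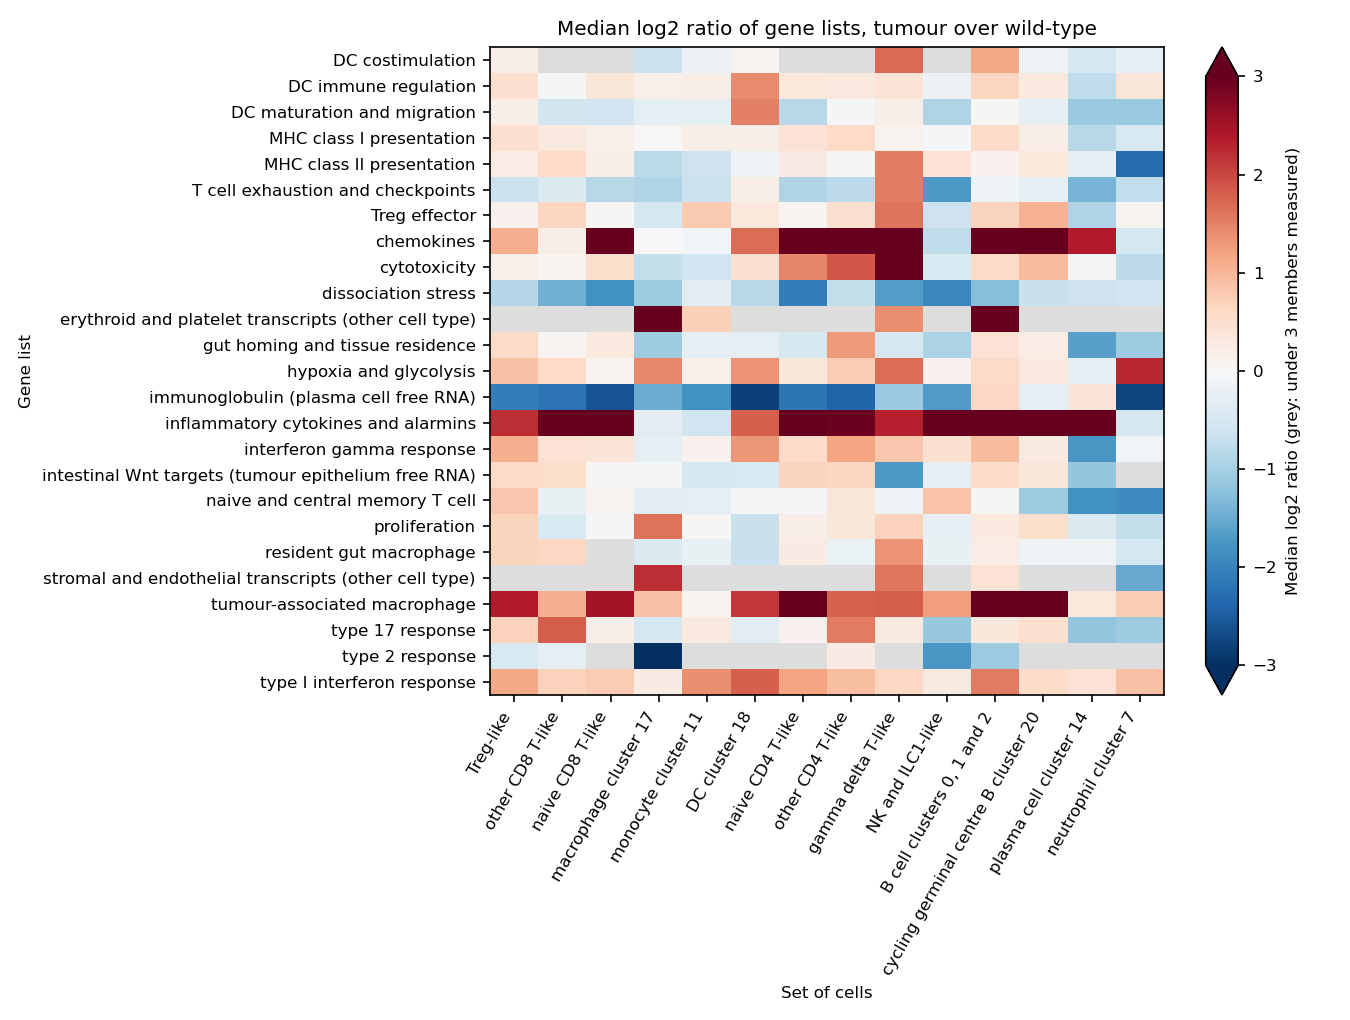
Median log2 ratio of tumour over wild-type for 25 gene lists (down) in 14 classes (across), coloured from lower in the tumour to higher in the tumour, with the colours limited at 3 on either side and grey where fewer than 3 genes were measured. The stress list lay below 0 in every class, from −2.08 to −0.32.

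Division genes were summed in each class. Treg had 2989.5 and 1973 CPM of them in the tumour and in normal colon, and the share of Treg with 2 or more such genes after thinning was 43.7% (37.1 to 50.5) and 41.1% (31.1 to 51.6). Germinal centre B cells had the highest level, 11682 CPM in the tumour and 8919 CPM in normal colon, with shares of 77.2% and 76.5%. B cells had less in the tumour, 1007 against 1312 CPM, with shares of 20.99% (19.4 to 22.6) and 28.0% (26.9 to 29.1). The median log2 ratio of the same list in B cells was 0.30 (0.14 to 0.45). It lay near the median of 0.27 over all genes measured in these cells, so no rise is read from it. Neutrophils of cluster 7 also had less, 806 against 1362 CPM, with shares of 11.996% and 25%. Among tumour DC, mregDC-like cells had 3819 CPM and a share of 54.9%, and the median of the list over the other DC was 0.61, with 7 of 14 genes higher, among them Tubb5, Tyms and Tk1, and 3 lower. Stmn1 and Ube2c were lower in them than in the other DC, by 5.52-fold (2.22 to 17.7) and 4.05-fold (1.22 to 21.1), and the interval of Mki67, 1.61-fold (0.789 to 3.53) lower, held 1. Naive wild-type T cells reached shares of 41.2% in CD8 and 37.3% in CD4 cells, so this share does not count dividing cells. In macrophages of cluster 17, the shares of 39.0% and 43.1% ran against the levels of 2377 and 1775 CPM, and no order is read from them.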

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

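No test was made of the differences below, and the assignment of left-out barcodes was the only check here written before its result was seen.

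Within each library, 4 gene lists had medians on opposite sides of 0 when Treg were set against the other CD4 T cells, and these differences between tumour and normal colon were not tested. Proliferation genes had a median log2 ratio of 0.87 in tumour Treg and −0.21 in wild-type Treg. Dissociation stress genes had 0.39 and −0.0153, tumour-associated macrophage genes 0.29 and −0.0171, and intestinal Wnt targets 0.0185 and −0.27. Only the proliferation values lay more than 1 apart, and each group had 1 library. The wild-type interval held 0 for all 4 lists. The called members leaned the same way in both libraries for proliferation, with 4 higher and 1 lower in normal colon, and for stress genes, with 9 higher and 4 lower there. With a median-of-ratios factor, macrophage genes had −0.0169 and −0.43 and Wnt targets −0.29 and −0.68, below 0 in both libraries.

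The authors' limit of 4000 genes left out cells that are not in the comparisons. Their assignment was checked on held-out cells for mregDC-like cells only, where it returned 80 of 85, and not for the other classes. Of 498 such tumour barcodes, with a median of 21910.5 UMIs, 206 were assigned to macrophages, 56 to monocytes, 32 to type 1 DC, 9 to mregDC-like cells and 4 to type 2 DC. With them, type 1 DC would be 51 of 482 tumour DC, 10.6% (7.98 to 13.7), where the kept cells gave 4.77%, and type 2 DC 4 of 482. Of 256 wild-type barcodes, with a median of 31643 UMIs, 164 were assigned to B cells and 28 to the mixed T and B cell class. Deep libraries of single cells and doublets both pass this limit, so these numbers do not count cells of a type.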

How the results depend on the processing

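All settings were chosen before the values were seen except the 16 added afterwards, and the cause of each shift was not tested.

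Of 2092 repeats of 350 gene ratios, 1975 stayed the same, 113 moved and 4 reversed. Of 1796 repeats of 315 list medians, 1473 stayed the same, 299 moved and 24 reversed. Of 116 repeats of 19 share results, 88 stayed, 26 moved and 2 reversed, and of 608 within 1 library, 387 stayed, 207 moved and 14 reversed. Of 14 proliferation shares, 13 stayed and 1 moved. That only called values can reverse was set after a first run was seen. Ratios below are tumour over wild-type, and medians and genes are log2.

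Without B cells, the largest class, the share ratios were 15.1 for neutrophils, 0.174 for T cells, 5.98 for monocytes, 2.14 for macrophages of clusters 13 and 17 together, 0.824 for those of cluster 17 and 1.75 for DC. In cells with 1000 UMIs or more, cluster 17 had 2.08. The B cell ratio was 0.268 without Scrublet doublets and 0.271 with own clustering. The tumour mregDC share was 48.7% by 2 of 4 marker genes and 88.3% among named DC (added). The Treg share by thinned Foxp3 UMIs was 10.7% in tumour and 6.68% in wild-type CD4 T cells, and the wild-type share was 17.01% at another Leiden resolution (added). Without thinning, the B cell proliferation share ratio was 0.848.

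The values of this paragraph were added. The tumour mregDC share was 54.96% without DC over the neutrophil score limit. The Treg share was 53.5% in the tumour from 80 CPM of Foxp3. In normal colon, it was 16.6% with mixed sub-clusters named by their T cell genes and 30.8% with that at the other resolution without the rule on leading genes. The ratio of the Treg share of the T cell class was 4.36 at the other resolution, 4.25 from 80 CPM of Foxp3 and 1.396 with mixed sub-clusters named at the other resolution. In that order of the last 2, other CD4 T cells had 2.03 and 1.44, and 1.02 with mixed sub-clusters named at the main resolution. Other CD8 T cells had 0.435 at the other resolution without the rule on leading genes, 0.377 with mixed sub-clusters named there and 0 with γδ T cells from 200 CPM of Trdc, and γδ T cells 0.9696 in that setting, where Gzma had −0.14, cytotoxicity genes 0.47 and gut homing genes 0.0429 in them.

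With members of 100 UMIs or more, the medians were −0.10 for Treg effector and −0.32 for resident macrophage genes in Treg. Resident macrophage genes had 0.18 in macrophages and 0.60 in DC. Type 17 genes had 4.66 in other CD4 T cells, interferon gamma genes −0.16 in NK cells, and gut homing and type I interferon genes −0.63 and 1.08 in B cells. Chemokines had −2.97 in plasma cells and 1.06 in neutrophils, and inflammatory genes −0.75 in neutrophils.

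With members of 1 UMI or more, the medians were 0.15 for proliferation in other CD8 T cells, −0.0258 for stromal genes in macrophages, −0.32 for erythroid genes in monocytes and −0.15 for cytotoxicity in DC. In γδ T cells, type I interferon genes had −0.19 and chemokines −0.15. Wnt targets had 0.22 in plasma cells and inflammatory genes −0.75 in neutrophils.

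Without members under 10% of their highest class (added), type I interferon genes had −0.24 in macrophages and 1.05 in B cells, DC maturation genes 0.56 in DC, Wnt targets −0.21 in naive CD4 T cells, gut homing genes −0.63 in B cells and Treg effector genes −0.22 in germinal centre B cells. Without Scrublet doublets, MHC class II genes had −0.0195 in NK cells. By the authors' normalized values, Ctss had −0.32 and Pf4 −0.11 in macrophages.

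With the median-of-ratios factor, naive genes had −0.18 in naive CD4 T cells and cytotoxicity genes −0.60 in NK cells. In B cells, MHC class II genes had −0.12, type I interferon genes 1.33 and resident macrophage genes −0.0105. In plasma cells, Pdia3 had 0.0193, hypoxia genes 0.10 and immunoglobulin genes 0.73. In neutrophils, MHC class I genes had 0.0658 and inflammatory genes −0.00616. MHC class II genes of mregDC-like cells over other DC had −0.98. Without DC 0 (added), they had −1.17, costimulatory genes 2.43, immune regulation genes 0.43, chemokines 2.34 and tumour-associated macrophage genes 0.18, and Arg1 had 0.27, Ccl17 3.54, Cd9 0.63, Cxcl10 4.01, Hspe1 −0.0199 and Il1rn 2.02. With the median-of-ratios factor, for Treg over other CD4 T cells of the tumour, gut homing genes had 1.08, type 2 genes 1.40, inflammatory genes −0.0675, tumour-associated macrophage genes −0.0169, Cxcl2 −0.10 and Ifi27l2a −0.000507. In normal colon, MHC class II genes had −0.00371 and type 2 genes 4.68. Without the sub-cluster at 80 to 100 CPM of Foxp3 (added), type 2 genes of tumour Treg had 4.06.

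Leaving out mixed clusters or cells over the tumour doublet threshold, both added, moved none of the 7 share results they were run on. Equal weight per cell gave a value for 324 of 350 gene ratios, and 271 of 315 lists kept 3 members at 100 UMIs.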

Other observations

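All tests below were chosen after the result was seen, except the checks of the authors' limits on cells.

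Ligands and receptors between mregDC and Treg were read from their levels in the tumour library. Ccl22 was at 2001 CPM (1933 to 2071) in mregDC-like cells and 539 CPM in the other DC, against 29.2 CPM in macrophages of cluster 13 and 3.29 CPM in B cells. Ccl17 had its highest level, 1399.8 CPM, in the other DC, most of them of a sub-cluster with neutrophil genes, with 933.7 CPM in mregDC-like cells and 164 CPM in macrophages of cluster 13. Their receptor Ccr4 was at 81.5 CPM (65.1 to 101) in Treg and 45.4 CPM (33.9 to 59.5) in other CD4 T cells, and had 1 count in naive CD4 T cells. Both partners were therefore transcribed in the tumour, but Ccr4 was not confined to Treg and stood at 114 CPM (83.5 to 151) in wild-type Treg. Il2ra was at 632 CPM in Treg, 278 CPM in γδ T cells, 151 CPM in other CD4 T cells and 129 CPM in mregDC-like cells. PD-L1, encoded by Cd274, was at 471 CPM in mregDC-like cells, 286 CPM in monocytes of cluster 5 and 134 CPM in neutrophils of clusters 3, 4 and 6. The mregDC-like cells were 144, those monocytes 1201 and those neutrophils 4748.

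Areg, a growth factor of epithelial repair, was highest in Treg and group 2 innate lymphoid cells in normal colon, and in γδ T cells and Treg in the tumour. In wild-type cells it was at 987 CPM in Treg, 948 CPM (892 to 1006) in group 2 innate lymphoid cells, 160 CPM in NK cells, 137 CPM in other CD4 T cells and 133 CPM in γδ T cells. In the tumour it was at 667 CPM (628 to 708) in γδ T cells and 431 CPM (393 to 473) in Treg, with 8.72 CPM in other CD4 T cells and 0 counts in NK cells. The 13 group 2 innate lymphoid cells of the tumour were too few for a level. Il10 was lower in its sources in the tumour, with 109 CPM in Treg against 1214 CPM in wild-type Treg, and 1.18 CPM in macrophages of cluster 17 against 108 CPM. These genes were picked after their values were seen.

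Stress genes were higher in the wild-type library in every class. Their list had a median below 0 in 14 of 14 classes, naive T cells included. That median is the pattern itself, so it does not decide for or against the handling of the 2 tissues. Free RNA of 1 source in the wild-type library was argued against, since 20 of 20 genes of the pattern changed their ratio to Hspa1b by 3 times or more between classes, in a test widened to all genes of the pattern, with a minimum of counts, after a first version with Hspa1b and Irs2 alone was seen. Tumour against normal tissue and handling cannot be told apart with 1 library per group.

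The wild-type library held few mregDC-like cells. Counting error was argued against, since the upper bound of the wild-type share was 15.4% and the lower bound of the tumour share 31.5%. The authors' limit of 4000 genes was argued against as well: with the barcodes over it, the wild-type share was 4.44% with an upper bound of 10.99%, and the tumour share 31.7% (27.6 to 36.1). That assignment returned 80 of 85 held-out mregDC-like cells, 3 of them wild-type, and put 94 held-out DC in that class. The check of the authors' mitochondrial limit could not decide. Of the 554 wild-type and 856 tumour barcodes over it, 55 and 25 were assigned to DC, 1 and 2 of these to mregDC-like cells. With those assigned to DC added, the wild-type share was 3.45% with an upper bound of 7.86%, and the tumour share 30.6% (26.6 to 34.8). The wild-type denominator grew by 51 barcodes assigned to type 2 DC, which lowers that bound. Of the tumour barcodes, 324 were assigned to the mixed T cell and neutrophil class, whose kept cells had a median of 8199 UMIs. Since the other classes were not checked at this depth, these values do not argue against the limit. The 554 and 856 barcodes had medians of 867.5 and 925 UMIs. Thinned to that depth, 79 of 82 held-out tumour mregDC-like cells were returned, but 1 of 3 in the wild-type library, so that side of the control rests on few cells. Barcodes with 200 genes or fewer were not examined. Tumour against normal tissue cannot be told apart from digestion with 1 library per group, and whether mregDC leave normal colon or are lost from it stays open.

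Cluster 23, called neutrophils by the authors, carried B cell and neutrophil genes together. Its median of 7118 UMIs was 0.968 times the sum of the medians of tumour B cells and neutrophils, 7351, which is in the range that doublets would give. Free neutrophil RNA in B cells was argued against, since S100a8 was 28.0-fold (27.5 to 28.6) above B cell cluster 2. Scrublet called 92.5% of its tumour cells doublets. Cells that took up neutrophil material stay open as an explanation that was not tested.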
